A study of Mus musculus with 18 samples.

How the data were processed

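RNA of sorted cells from mouse embryos was sequenced in 18 libraries, per the labels' protocols. About 10 homozygous embryos were pooled for a sort, 2500 to 5000 cells were sorted, and RNA equal to that of 1000 cells entered a SMART-Seq2 library, which was read from 1 end for 75 bases. SMART-Seq2 does not record strand, so reads of overlapping genes on opposite strands cannot be told apart. The mice had a mixed background, embryos were not sexed, and the extra-embryonic part had been cut off for genotyping, per the labels. The labels call the samples biological replicates and do not say whether samples with equal numbers shared a day or a litter.

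The authors deposited 1 table of signal, gene read counts divided by 1 size factor per library. STAR 2.5.2a, HTSeq 0.6.1, DESeq and DESeq2 and the genome build mm10 are named in the submitters' processing notes, with no settings; the annotation is not given in the sources used here. The table had 24503 lines, of which 5 were HTSeq's counters and 24498 genes. The counters stayed out of all tests. As shares of all that was counted, 7.17% to 12.1% had no feature, 0.495% to 0.756% were ambiguous and 37.7% to 41.3% were not unique. Every value was a whole multiple of what 1 read is worth: 441054 of 441054 values were whole within 1e-06 reads, and 1 read was worth 0.825 to 1.37. The size factors differed from those of the median of ratios by at most 0.000205 in relative terms. The largest gene, Rn45s, a ribosomal RNA precursor, held 23.7% to 44.0% of the reads in genes. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 5.12 to 105), so no library was counted as a copy of another.

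Genes with a value of at least 10 in at least 3 libraries were tested, 14711 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) in 1 model with 6 group means over all 18 libraries, with a trend in the variance. Each gene thus has 1 spread for all 6 groups, also where the compared groups varied more than the others. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. Contrasts were ΔHx against WT in each gate, the gates within each genotype, and the differences of genotype effects between gates. Of 38 gene lists 37 had at least 4 tested members and were tested with camera at a correlation of 0.01, adjusted over the lists of a contrast; they were also tested with an estimated correlation and with fry. Genes that differed at least 2-fold between 2 WT gates were tested as sets in the third gate, 6 sets in all. Equal replicate numbers were not treated as pairs.

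The design, the lists, the alternatives and the rule for named genes were chosen before the data were examined. That rule took Foxa2, and for each genotype contrast up to 8 rises and 8 falls, the largest in log2 among called genes with a mean of at least 20 in the higher group and non-overlapping libraries. It added up to 3 members of each list with at least 2 called members or that passed the camera test, up to 6 rises and 6 falls for gate contrasts in WT, and for differences between gates the 5 smallest adjusted p on each side. Predicted and clone-named genes were left out of the largest changes. Genes called in at least 2 gates, and others where so stated, were named after their values were seen. For a lower bound on a fold, a group at 0 reads was given a floor of 3 reads in each library. Ratios with 1 to 3 reads in a group use the reads counted and have exact 95% intervals, so a bound and a ratio are not on the same footing. Positions are those of genes with 1 position in the GENCODE annotation of mm10, which held 14268 of the 14711 tested genes.

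Alternatives were pseudocounts of 0.5 and 5, no filter and a filter at 50, quantile normalisation, libraries rescaled to equal totals, a model of the compared groups alone, a replicate block, array weights, robust variances, a 2-fold limit, and tests of the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0. The equal totals included Rn45s, whose share differed between libraries, and totals without it were not tried. Each library of the compared groups was also left out in turn. On the recovered reads edgeR called 8 rises and 8 falls in High, 11 and 63 in Mid and 9 and 14 in Neg. The steps were tested on simulated data for the High genotype comparison, with 14479 genes. Of 100 genes changed 2-fold 67 were recovered, and of 100 changed 4-fold 90 were, with 0 in the wrong direction and 7 unchanged genes among 164 calls. A list of changed genes was called, and 0 of 19 unchanged lists were. Simulated genes varied independently of each other and all genes of the changed list rose. This therefore does not show how the list test behaves for genes that vary together, as in the real lists.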

Results

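RNA was profiled in cells of mouse embryos at embryonic day 7.5, during gastrulation, that carried FoxA2 fused to a red fluorescent protein (tagRFP) on both alleles. FoxA2 is a forkhead transcription factor of endoderm, node and notochord. The fused protein was either intact (WT) or lacked 10 amino acids that form an α-helix (ΔHx), a part that the series describes as needed to activate target genes. Cells were sorted by red fluorescence into 3 gates. High lay above the signal of heterozygous cells, Mid lay above autofluorescence and reached the heterozygous maximum, and Neg held cells without signal. Each of the 6 combinations of genotype and gate had 3 biological replicates, giving 18 libraries. Libraries held 12302196 to 17194136 reads in genes, and 15649 to 17917 genes had a read. One library, ΔHx High replicate 3, had the fewest genes with a read, and 264 of its 3967 low genes had none, against 25 to 141 in the other libraries. Values below are normalised read counts, given as mean ± SD of n = 3 libraries, and changes are on the log2(value + 1) scale, which understates those of low genes. Lower bounds on folds set a group without reads to a floor of 3 reads in each of its libraries. Intervals and bounds cover counting error only.

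**Figure D1:**
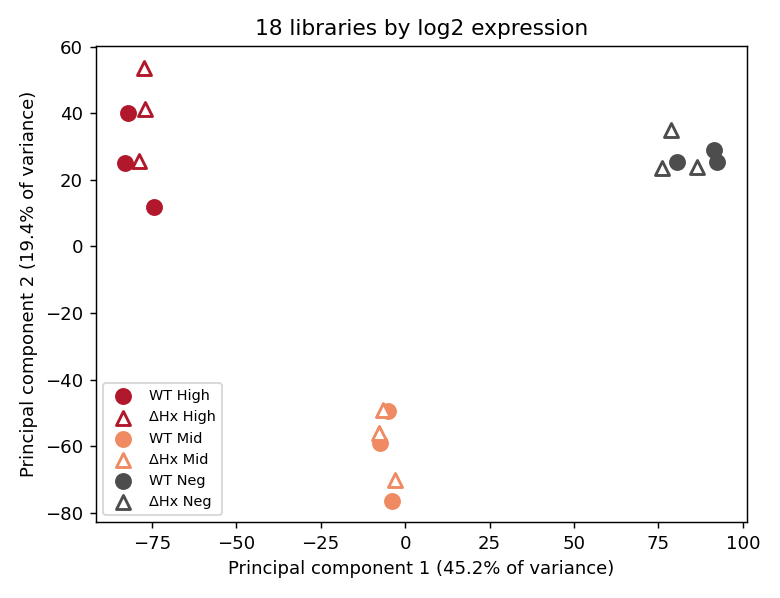
Positions of the 18 libraries on the first and second principal components of log2 expression, in arbitrary units; filled circles are WT, open triangles ΔHx, and colours mark the gates. The components held 45.2% and 19.4% of the variance and set the 3 gates apart, with both genotypes of a gate side by side.

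The targeted gene, Foxa2 (mm10, chromosome 2, 148042877 to 148046969, minus strand, protein coding), followed the gates in every library. Its values were 2483, 1742 and 1556 in the WT High libraries and 1848, 2078 and 2385 in ΔHx High. They were 871, 812 and 621 in WT Mid and 547, 611 and 1229 in ΔHx Mid. In Neg they were 40.6, 20.3 and 23.6 in WT and 62.5, 55.0 and 43.4 in ΔHx. Within a gate the genotypes did not differ past the threshold: the log2 change from WT to ΔHx was 0.15 (SE 0.28, adjusted p = 0.927) in High, -0.03 (SE 0.28, adjusted p = 0.996) in Mid and 0.95 (SE 0.28, adjusted p = 0.405) in Neg. A value per gene checks the gates and not the deletion, because the ΔHx allele keeps the rest of the gene.

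The first question was which cells each gate held in WT embryos. The High gate was marked by node, notochord and ciliary genes. All 16 tested genes of the node and notochord list rose from Neg to High (adjusted p = 0.00536 with an estimated correlation), as did all 25 of the motile cilia list (adjusted p = 0.0152 with an estimated correlation). Shh, a signalling protein of the notochord, was 2721 ± 1066 in High and 2.05 ± 3.56 in Neg. Noto, a homeobox gene of the node, was 2329 ± 567 against 6.65 ± 8.18, and Foxj1, the main regulator of motile cilia, was 5123 ± 1273 against 33.8 ± 33.3. Of 17 definitive endoderm genes 11 rose and 1 fell (adjusted p = 0.0233 with an estimated correlation), among them Cer1 (11433 ± 1437 against 286 ± 81.8), Foxa1 (941 ± 308 against 7.74 ± 9.30) and Krt19 (4134 ± 1184 against 133 ± 24.2). Mesoderm genes were low in High. Of 21 lateral, cardiac and extra-embryonic mesoderm genes 20 fell (adjusted p = 0.00536 with an estimated correlation), as did 18 of 19 nascent and paraxial mesoderm genes (adjusted p = 0.0253 with an estimated correlation) and 15 of 18 blood and endothelial genes (adjusted p = 0.0233 with an estimated correlation). Hand1 was 12.1 ± 8.20 against 1501 ± 185, Foxf1 was 3.71 ± 4.28 against 411 ± 31.9, and Mesp1 was 37.5 ± 25.3 against 916 ± 80.9. Hox genes were also low, with 21 of 22 below Neg (adjusted p = 0.0253 with an estimated correlation). In all, 3331 genes rose and 3201 fell of 14711 tested, and 54.7% of genes had non-overlapping libraries, where chance gives 10%.

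The WT Mid gate held high levels of visceral and parietal endoderm genes. From Neg to Mid, 24 of 25 visceral endoderm genes rose (adjusted p = 0.0319 with an estimated correlation). Transthyretin, Ttr, was 5584 ± 656 against 163 ± 7.07, Apob was 6382 ± 789 against 161 ± 3.78, and the transcription factor Hnf4a was 540 ± 77.5 against 10.5 ± 2.15. All 11 parietal endoderm genes rose (adjusted p = 0.102 with an estimated correlation), with a wide spread between replicates in genes such as Lama1 (13716 ± 14241 against 608 ± 90.6). Definitive endoderm genes were raised too, 12 of 17 passing the test (adjusted p = 0.00814 with an estimated correlation), including Spink1 (6785 ± 1138 against 182 ± 52.8) and Tmprss2 (3614 ± 1043 against 146 ± 80.5). Both lists rose in the same libraries, so this does not show definitive endoderm cells beside visceral ones. From Mid to High, all 16 node genes (adjusted p = 0.00925 with an estimated correlation) and all 25 ciliary genes (adjusted p = 0.0150 with an estimated correlation) rose. Over the same step 17 of 19 nascent and paraxial mesoderm genes fell (adjusted p = 0.0150 with an estimated correlation), as did 23 of 25 visceral endoderm genes (adjusted p = 0.0845 with an estimated correlation). The endocytic receptor Cubn was 465 ± 361 in High against 8507 ± 949 in Mid. Between Mid and Neg 2567 genes rose and 2267 fell, and between High and Mid 1774 rose and 1819 fell. With libraries rescaled to equal totals, where the median log2 change of all genes was -0.17 and 0.11 against -0.00180 and -0.0139 before, these splits were 1889 against 2876 and 1873 against 982. Those totals include Rn45s, which held 28.6% to 44.0% of reads in WT Mid, 23.7% to 32.1% in WT Neg and 29.0% to 37.9% in WT High. This setting therefore also scales all genes by the Rn45s share of their library.

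Gate differences in ΔHx embryos were close to those in WT in their pattern across genes. From Neg to High 3160 genes rose and 3103 fell in ΔHx, from Neg to Mid 2632 rose and 2421 fell, and from Mid to High 1959 rose and 1810 fell (2176 and 1141 with equal totals, where the median log2 change of all genes was 0.13 against -0.00751 before). Both genotypes called 5187 genes in the same direction and 0 in opposite directions between High and Neg, where independent calls would give 1390.7 in the same direction. The counts were 3647 and 1 between Mid and Neg (832.4 if independent) and 2386 and 2 between High and Mid (460 if independent). Across genes, which are not independent replicates, Pearson's r of the WT and ΔHx log2 changes was 0.906, 0.829 and 0.796.

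**Figure D2:**
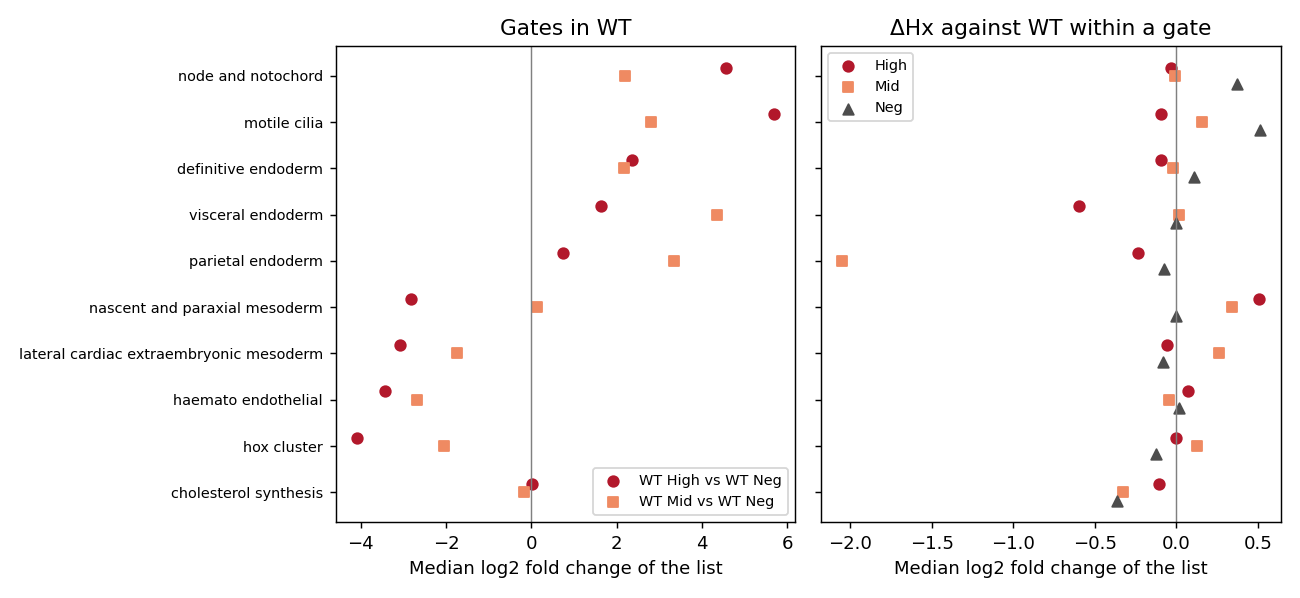
Median log2 fold change of 10 gene lists, between gates in WT (left) and from WT to ΔHx within each gate (right, on an axis of its own scale). Node and ciliary lists had medians of 4.57 and 5.70 between WT High and Neg, while the furthest genotype median was -2.05, for parietal endoderm genes in the Mid gate.

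The second question was what the helix deletion changed within each gate. In the High gate 9 genes rose and 9 fell in ΔHx, and 1157 of 14711 had an unadjusted p under 0.05, a share above the 0.05 that chance alone gives. Genes vary together, so such a share is not a test. Dll1, a Notch ligand of the presomitic mesoderm, rose from 696 ± 145 to 1483 ± 165 (log2 1.10, SE 0.15, adjusted p = 0.00129). The extracellular matrix protein Reln was 171 ± 26.5 against 69.5 ± 10.5 (adjusted p = 0.0449), and the receptor kinase Tyro3 was 1670 ± 373 against 985 ± 43.8 (adjusted p = 0.0303). Among the falls, Gprc5a, an orphan receptor, went from 237 ± 82.7 to 52.8 ± 27.4 (log2 -2.19, SE 0.34, adjusted p = 0.00678). Nepn, a gene of gut endoderm that was singled out after its values were seen, had 49 reads in WT and 3 in ΔHx, a ratio of 18.5 (95% interval 5.95 to 92.5). Of the 18 calls 6 were kept in every fit that left out 1 of the compared libraries, those of Dll1, Nr1h5, A530016L24Rik, Cap1, Hyou1 and Extl3. The call of Gprc5a ended without ΔHx High replicate 1 (adjusted p = 0.0575), ΔHx High replicate 3 (0.0522) or WT High replicate 2 (0.0839), that of Nepn without ΔHx High replicate 3 or WT High replicate 2 (up to 0.0839), that of Tyro3 without any library but ΔHx High replicate 2 (up to 0.151) and that of Reln without any of the 6 (up to 0.169). Without ΔHx High replicate 1 there were 4 rises and without ΔHx High replicate 3 there were 3 falls, and a model of the 6 High libraries alone called 3 genes but not Dll1, Reln, Tyro3, Gprc5a or Nepn (adjusted p 0.112 to 0.280). Reln was also not called by edgeR (adjusted p = 0.0539) or with a pseudocount of 5 (0.0505).

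In the High gate 7 gene lists were called, and 0 were with an estimated correlation (lowest adjusted p = 0.702). Visceral endoderm genes were called lower as a list (median log2 -0.60, adjusted p = 9.17e-10), although 0 of 25 passed over all genes and 6 fell when adjusted over the list alone (adjusted p = 0.702 with an estimated correlation). The foetal albumin-like protein Afp was 216 ± 144 in ΔHx and 643 ± 314 in WT, and the iron carrier Trf was 89.2 ± 44.1 and 204 ± 18.1. The median of this list was -0.24 without WT High replicate 2, -1.02 without ΔHx High replicate 2 and -0.95 without WT High replicate 3. Nascent and paraxial mesoderm genes were called higher (median 0.50, adjusted p = 3.89e-06), with 1 of 19, Dll1, passing over all genes and 7 adjusted over the list alone (adjusted p = 0.702 with an estimated correlation). Msgn1 was 82.1 ± 27.5 against 31.8 ± 6.77 and Mesp1 was 74.0 ± 37.0 against 37.5 ± 25.3. The endoderm organ list (median -0.46, adjusted p = 0.0202) was called lower (adjusted p = 0.782 with an estimated correlation), with 2 of 12 falling over the list alone. Without ΔHx High replicate 1 (median -0.27) or WT High replicate 2 (median -0.13) it was not called (adjusted p up to 0.186), and without WT High replicate 3 its median was -1.08. S phase genes were called higher (median 0.11, adjusted p = 0.0202) and mitotic genes lower (median -0.10, adjusted p = 0.0202), and core histone genes were called lower (median -0.16, adjusted p = 0.0298). With an estimated correlation these had adjusted p = 0.880 each. The S phase call ended without ΔHx High replicate 1 or WT High replicate 1 (adjusted p up to 0.475), the mitotic call without ΔHx High replicate 1, ΔHx High replicate 2 or WT High replicate 3 (up to 0.739), and the histone call without ΔHx High replicate 1 or 3 or WT High replicate 2 or 3 (up to 0.568) and with quantile normalisation (0.110). Where calls were kept, the S phase median was 0.19 without WT High replicate 3, the mitotic median -0.22 without ΔHx High replicate 3 and -0.17 without WT High replicate 1, and the histone median -0.32 without ΔHx High replicate 2. Where they ended, the S phase median was 0.00131 without WT High replicate 1. The mitotic median was -0.00773 without WT High replicate 3 and -0.06 without ΔHx High replicate 2. The histone median was -0.04 without ΔHx High replicate 3 and -0.24 without WT High replicate 3. Sex-linked genes differed beside these groups: the list was called higher (median 0.82, adjusted p = 0.0298), with 4 rises and 1 fall adjusted over the list alone (adjusted p = 0.702 with an estimated correlation), a call that ended without ΔHx High replicate 1, ΔHx High replicate 3 or WT High replicate 1 (up to 0.123). Xist, expressed from the inactive X, was 1600 ± 212 in ΔHx and 3613 ± 1428 in WT, and the Y-linked Eif2s3y was 478 ± 79.4 and 261 ± 38.0. The pools may thus differ in their share of female embryos between the genotypes. Embryos were not sexed, so effects of sex and of genotype cannot be told apart, here or in the other gates.

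In the Mid gate 11 genes rose and 48 fell, and 1171 of 14711 had an unadjusted p under 0.05, also a share above 0.05. Of 11 parietal endoderm genes 7 fell over all genes and 10 over the list alone (median -2.05, adjusted p = 1.91e-23), while the list missed the threshold with adjusted p = 0.0863 with an estimated correlation. Lama1, a laminin chain, was 1194 ± 216 in ΔHx and 13716 ± 14241 in WT (log2 -3.01, SE 0.44, adjusted p = 0.00375), with WT libraries at 30072, 4065 and 7011. This SE, like that of Nid1 below, comes from the spread over all 6 groups and understates that of the WT Mid libraries. Chi-square per degree of freedom between replicates was 28.7 to 105 in WT Mid and 5.1 to 7.3 in ΔHx Neg. The collagen chains Col4a1 (6404 ± 1154 against 34048 ± 30094, adjusted p = 0.0129) and Col4a2 (3207 ± 858 against 16135 ± 14335, adjusted p = 0.0155) fell too, as did Sparc (2750 ± 567 against 17312 ± 17650, adjusted p = 0.0184). Outside the list, the basement membrane protein Nid1 was 437 ± 116 against 7304 ± 7752 (log2 -3.55, SE 0.45, adjusted p = 0.000843). The noradrenaline transporter Slc6a2 had 3 reads in ΔHx and 709 in WT, a ratio of 240.6 (95% interval 82.0 to 1170). The transcription factor Sox7 was 54.1 ± 34.2 against 687 ± 692 (adjusted p = 0.0347). Col4a1, Col4a2, Nid1, Sox7 and Pax6 were singled out after their values were seen. Among the rises, the embryonic globin Hbb-bh1 had 81 reads in ΔHx and 0 in WT, at least 8.05-fold higher, and the neural gene Pax6 had 25 and 0, at least 2.56-fold higher. WT Mid replicate 1 had the highest parietal gene values; without it the list kept its call (median -1.35, adjusted p = 3.19e-23), and the log2 change was -1.36 for Col4a1 (-2.05 with it), -1.35 for Sparc (-2.17 with it) and -1.31 for Col4a2, each over 1.5 times smaller. The number of falls was 9 without ΔHx Mid replicate 2 and 117 without WT Mid replicate 2, and a model of the 6 Mid libraries alone called 3 genes, of those named here Slc6a2 only (adjusted p of the others 0.181 to 0.529). Without ΔHx Mid replicate 1 there were 3 rises. The calls of Col4a1, Col4a2 and Sparc ended without ΔHx Mid replicate 1 or 2 (adjusted p up to 0.0945), those of Sox7 and Pax6 without ΔHx Mid replicate 1 or 2 or WT Mid replicate 1 or 3 (up to 0.203 and 0.153), and that of Hbb-bh1 without any library but ΔHx Mid replicate 3 (up to 0.209). That of Hbb-bh1 also ended in edgeR (adjusted p = 0.177), with a pseudocount of 5 (0.191) and with no filter (0.0718), that of Pax6 with a pseudocount of 5 (0.0869), that of Sox7 with a pseudocount of 0.5 (0.0513) and with no filter (0.0640), and those of Col4a2 and Sparc with robust variances (0.0509 and 0.0585).

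Other lists in the Mid gate had smaller medians. The unfolded protein response list was called lower (median -0.31, adjusted p = 7.87e-05; adjusted p = 0.180 with an estimated correlation), with 0 of 14 members passing; Xbp1 was 1505 ± 16.5 in ΔHx and 1971 ± 399 in WT, and without WT Mid replicate 1 the median was -0.15 (adjusted p = 0.0170). Cholesterol synthesis genes were called lower (median -0.32, adjusted p = 8.29e-05; adjusted p = 0.655 with an estimated correlation), with 2 of 18 falling over the list alone, and without WT Mid replicate 3 the median was 0.04 (adjusted p = 0.679), and without WT Mid replicate 1 it was -0.68. Nascent and paraxial mesoderm genes were called higher (median 0.34, adjusted p = 0.0192; adjusted p = 0.655 with an estimated correlation), with 3 of 19 rising over the list alone, and epiblast genes lower (median -0.10, adjusted p = 0.0335; adjusted p = 0.655 with an estimated correlation). Both calls ended without ΔHx Mid replicate 1, ΔHx Mid replicate 2 or WT Mid replicate 2, the mesoderm call also without WT Mid replicate 3 and the epiblast call also without WT Mid replicate 1 (adjusted p up to 0.231 and 0.416). Without ΔHx Mid replicate 3 the mesoderm median was 0.54 and the epiblast median -0.40, and without WT Mid replicate 3 the epiblast median was -0.23. The mesoderm median was 0.17 without ΔHx Mid replicate 1. The epiblast median was 0.00215 without ΔHx Mid replicate 2, a turn of sign, and -0.04 without WT Mid replicate 2. Ribosomal protein genes were called higher (median 0.06, adjusted p = 0.0143; adjusted p = 0.918 with an estimated correlation), although the 1 member that passed, Rpl29, fell, and the call ended without ΔHx Mid replicate 3, WT Mid replicate 2 or WT Mid replicate 3 (adjusted p up to 0.939), while the median was 0.10 without ΔHx Mid replicate 1 and 0.13 without WT Mid replicate 1. Ribosomal genes have many near-identical copies and their counts are uncertain. Sex-linked genes were called higher in Mid too (median 1.28, adjusted p = 7.87e-05, and adjusted p = 0.0977 with an estimated correlation). The Y-linked Ddx3y was 549 ± 47.6 in ΔHx and 268 ± 159 in WT, and without WT Mid replicate 1 the median of the list was 0.73. That library held 63 Ddx3y reads, against 402 and 382 in WT Mid replicates 2 and 3, and 5903 Xist reads, against 4886 and 2098.

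In the Neg gate 20 genes rose and 16 fell. An unadjusted p under 0.05 was found for 614 of 14711 genes, a share below the 0.05 that chance alone gives. Shh was 40.2 ± 17.4 in ΔHx and 2.05 ± 3.56 in WT (log2 4.31, SE 0.62, adjusted p = 0.00323), levels far below those of the High gate. Nodal, the ligand that patterns the node, was 127 ± 21.1 against 64.5 ± 20.6 (log2 1.01, SE 0.20, adjusted p = 0.0392). The node and notochord list was called higher (median 0.37, adjusted p = 1.66e-07), with 2 of 16 rising over all genes and 4 over the list alone (adjusted p = 0.184 with an estimated correlation). The motile cilia list was called higher (median 0.51, adjusted p = 7.40e-07), with 1 of 25, Spag6l, rising over all genes and 3 over the list alone (adjusted p = 0.457 with an estimated correlation). Without ΔHx Neg replicate 1 the medians of these lists were 0.25 and 0.30, and without ΔHx Neg replicate 3 that of the cilia list was 0.79. Spag6l had 12 reads in ΔHx and 0 in WT, at least 1.32-fold higher. Outside the lists, the ciliary genes Rsph4a (45 reads against 3, ratio 14.8, 95% interval 4.76 to 74.6) and Zmynd10 (19.2 ± 11.1 against 2.10 ± 2.64, adjusted p = 0.0103) were singled out after their values were seen. Prl3d1, a placental lactogen of trophoblast giant cells, had 3 reads in ΔHx and 92 in WT, a ratio of 31.0 (95% interval 10.3 to 153). Trophoblast genes were called lower as a list (median -0.27, adjusted p = 0.0144; adjusted p = 0.457 with an estimated correlation), with Prl3d1 the 1 member of 13 that fell. The call of Shh held in every fit that left out 1 library (adjusted p up to 0.0354) but not in edgeR (adjusted p = 0.124) or in a model of the 6 Neg libraries alone (0.0711). Nodal lost its call in all such fits but that without WT Neg replicate 2, with adjusted p up to 0.237 without ΔHx Neg replicate 3. The calls of Rsph4a and Zmynd10 ended without ΔHx Neg replicate 1, ΔHx Neg replicate 2 or WT Neg replicate 3 (up to 0.205 and 0.111), that of Spag6l without any library but ΔHx Neg replicate 3 (up to 0.283) and that of Prl3d1 without any but ΔHx Neg replicate 1 (up to 0.258). These 4 genes and Nodal were not called by edgeR (adjusted p 0.111 to 0.571) or in the model of the Neg libraries either (0.0506 to 0.331). The calls of Rsph4a and Spag6l also ended with a pseudocount of 5, that of Prl3d1 with a pseudocount of 0.5 (0.118), those of Nodal and Spag6l with no filter, quantile normalisation or equal totals (up to 0.0639 and 0.0936), and that of Spag6l in DESeq2 (0.120). The trophoblast call ended without ΔHx Neg replicate 2, WT Neg replicate 2 or WT Neg replicate 3 (up to 0.122). There were 8 rises without ΔHx Neg replicate 1, and 2 falls without WT Neg replicate 3.

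Cholesterol synthesis genes were also called lower in the Neg gate (median -0.36, adjusted p = 9.09e-07; adjusted p = 0.669 with an estimated correlation), with 0 of 18 passing, and without WT Neg replicate 3 the median was -0.02 (adjusted p = 0.541), and without WT Neg replicate 1 it was -0.60. Hypoxia and glycolysis genes were called higher (median 0.12, adjusted p = 0.0496; adjusted p = 0.871 with an estimated correlation), which ended without ΔHx Neg replicate 1, ΔHx Neg replicate 2 or WT Neg replicate 1 (adjusted p up to 0.821) and with quantile normalisation (0.0760). Sex-linked genes were called higher (median 0.72, adjusted p = 0.0273; adjusted p = 0.457 with an estimated correlation), with Xist at 1414 ± 561 in ΔHx and 2433 ± 844 in WT; the call ended without ΔHx Neg replicate 2 or 3 or WT Neg replicate 2 or 3 (up to 0.123). In genotype comparisons the share of genes with non-overlapping libraries was 10.9% in High, 10.9% in Mid and 12.7% in Neg, where chance gives 10%.

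Some genes differed between the genotypes in more than 1 gate. Of 91 genes called in any gate, 15 were called in at least 2 and 7 in all 3. These 7 were Alox15, Cap1, Hyou1, Lpar2 and A530016L24Rik, which rose, and Nr1h5 and Gm1821, which fell. Nr1h5 (chromosome 3, 102939658 to 102964133, minus strand, protein coding), a nuclear receptor, had 0 reads in ΔHx High and Mid and 7 in ΔHx Neg, against 389, 811 and 847 in WT, so that it was at least 52.4-fold lower in High and at least 104.8-fold lower in Mid. Alox15 (chromosome 11, 70344152 to 70352031, minus strand, protein coding), a lipoxygenase, was 461 ± 58.5 against 86.9 ± 80.0 in High, 175 ± 32.9 against 13.4 ± 4.49 in Mid and 537 ± 116 against 40.6 ± 20.1 in Neg. In High its call ended without ΔHx High replicate 1 or 3 or WT High replicate 2 or 3, with adjusted p up to 0.0852. The calls of Nr1h5, Alox15 in Mid and Neg, and Cap1 held in every fit without 1 library. That of A530016L24Rik in Neg ended in all but the fit without WT Neg replicate 2 (up to 0.139), that of Hyou1 in Mid without ΔHx Mid replicate 1 or 2 or WT Mid replicate 2 (up to 0.109), and those of Lpar2 in 5, 4 and 5 of 6 fits in High, Mid and Neg (up to 0.124 without ΔHx High replicate 1, 0.111 without ΔHx Mid replicate 3 and 0.0996 without WT Neg replicate 3). That of Gm1821 ended in High without ΔHx High replicate 3 (0.0522), in Mid without ΔHx Mid replicate 1 or 2 (up to 0.0616) and in Neg without ΔHx Neg replicate 1 or 2 or WT Neg replicate 2 or 3 (up to 0.118). With libraries rescaled to equal totals Hyou1 was not called in Mid or Neg. A model of the compared groups alone ended the calls of Cap1, Hyou1, Lpar2 and Gm1821 in High and Mid, Alox15 in High and A530016L24Rik in Mid and Neg (adjusted p 0.0564 to 0.427), and edgeR did not call A530016L24Rik in Neg (0.111). Hyou1, a chaperone of the endoplasmic reticulum, was 2512 ± 241 against 1356 ± 121 in High. High and Neg shared 5 rises and 4 falls, where independent lists would share 0.0122 and 0.00979. These 2 comparisons use no library in common, but their gates may have been sorted from the same pools of embryos, which the labels do not say. A difference between pools would then recur in both gates, so the shared calls are not independent replication. Gm1821, Rpl29 and Hspa8 have similar copies elsewhere, and their counts are uncertain.

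**Figure D3:**
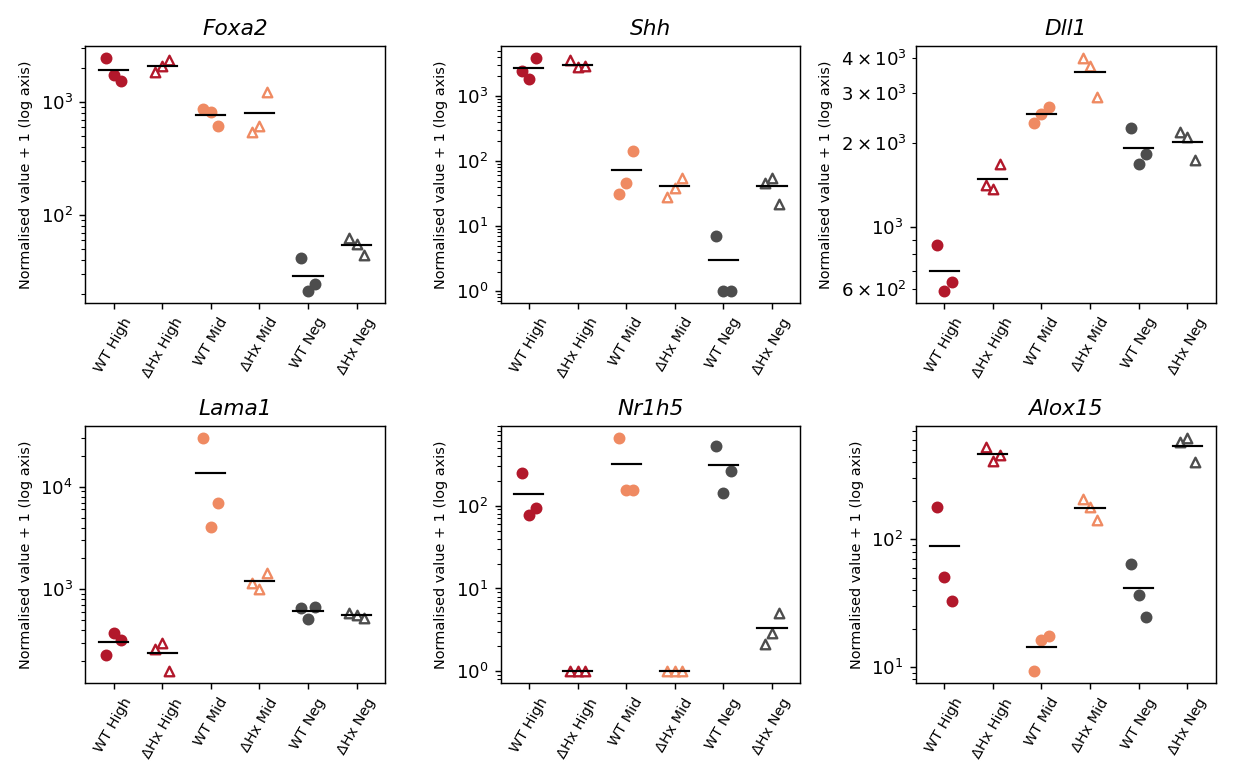
Normalised read count + 1 on a log axis of 6 genes in each library, by genotype and gate; circles are WT, triangles ΔHx, and black lines the mean of 3 libraries. Nr1h5 and Alox15 differed in all 3 gates, Dll1 was called in High, Lama1 in Mid and Shh in Neg.

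Whether a genotype effect differed between gates was tested directly. Limma called 0 genes for High against Neg (0 by edgeR and 6 by DESeq2), where 463 of 14711 had an unadjusted p under 0.05, a share below the 0.05 that chance alone gives. It called 2 for High against Mid, Nid1 and Slc6a2, and 1 for Mid against Neg, Slc6a2. For the other genes named in 1 gate, such as Dll1 and Shh, the difference between gates did not pass the test. Genes that separated the WT gates, taken each time from WT libraries outside the comparison, were also tested as sets. The 1530 genes higher in WT Mid than in WT Neg were called lower in ΔHx High (median -0.13, adjusted p = 0.000824; adjusted p = 0.216 with an estimated correlation), with a median of -0.06 (adjusted p = 0.0306) without ΔHx High replicate 3. The 1119 genes higher in WT High than in WT Mid were called higher in ΔHx Neg (median 0.08, adjusted p = 0.0197; adjusted p = 0.847 with an estimated correlation), a call that ended without ΔHx Neg replicate 1 or 2 or WT Neg replicate 2 or 3, with adjusted p up to 0.270 without ΔHx Neg replicate 1. Without ΔHx Neg replicate 3 or WT Neg replicate 1 its median was 0.13. The other 4 sets were not called.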

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

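The test of carried-over cells below was chosen after the result was seen. The genotype effect on Nid1, a basement membrane protein, differed between High and Mid by 3.99 (log2, SE 0.64, adjusted p = 0.0422), which stood out as a difference between gates: it was 445 ± 122 in ΔHx High and 329 ± 91.3 in WT High, and fell in Mid (log2 -3.55). That of Slc6a2, the noradrenaline transporter, differed by 7.09 (SE 1.07, adjusted p = 0.0359) between High and Mid and by -7.62 (SE 1.07, adjusted p = 0.0133) between Mid and Neg. Both genes were low in ΔHx Mid: Nid1 had 303, 496 and 512 against 16229, 2245 and 3437 in WT Mid, and Slc6a2 had 1.86, 0 and 1.14 against 482, 165 and 160. The Nid1 call ended in 9 of 12 fits that left out 1 library, all but those without a WT Mid library (adjusted p up to 0.221 without ΔHx Mid replicate 1). Those of Slc6a2 ended in 8 of 12 fits for High against Mid, all but those without ΔHx High replicate 3, WT High replicate 1, WT Mid replicate 2 or WT Mid replicate 3 (up to 0.119 without ΔHx Mid replicate 2). For Mid against Neg it ended without ΔHx Mid replicate 2, ΔHx Neg replicate 2 or 3 or WT Neg replicate 3 (up to 0.0730 without ΔHx Neg replicate 2). All 3 calls also ended with a pseudocount of 0.5 and a filter at 50 (adjusted p up to 0.148). That of Nid1 further ended with no filter, the compared groups alone or robust variances (up to 0.576), those of Slc6a2 in edgeR (up to 0.277), and that for High against Mid with the compared groups alone (0.144).

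Nid1 and Slc6a2 fell in ΔHx Mid, as did 7 of 11 parietal endoderm genes (adjusted p = 0.0863 for the list with an estimated correlation). WT Mid replicate 1 alone does not account for this, because without it the parietal list was still called lower (median -1.35 against -2.05 with it, adjusted p = 3.19e-23). Cells of 1 other source, carried over in differing amounts, would make other falling genes peak in the same library: 85.4% of the 41 called falls outside the list were highest in WT Mid replicate 1, against 36.7% of all tested genes, which is consistent with carry-over of parietal endoderm cells left on WT embryos at dissection, where the extra-embryonic part had been cut off; Sparc and Col4a1, abundant in the parietal list, were 17312 and 34048 in WT Mid, but such cells would have to pass the Mid gate by their red fluorescence, which was not tested, and Lama1 was 13716 in WT Mid against 608 in Neg and 305 in High. These 41 genes were picked as falls, so this share may be raised by their selection, and a lack of such cells in ΔHx embryos stays open beside unequal dissection, since no value here separates them. The trophoblast list, of another extra-embryonic tissue, was called lower in ΔHx Neg (median -0.27, adjusted p = 0.0144; adjusted p = 0.457 with an estimated correlation), with Prl3d1 (3 reads against 92) the 1 member of 13 that fell, and was not called in Mid (adjusted p = 0.917); both Neg calls ended without ΔHx Neg replicate 2 (list median -0.14) or WT Neg replicate 2 or 3, and that of Prl3d1 also without ΔHx Neg replicate 3 or WT Neg replicate 1 (up to 0.122 and 0.258).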

How the results depend on the processing

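The setting without 3 libraries that stood apart on principal components (ΔHx High replicate 3, ΔHx Mid replicate 3 and WT Mid replicate 1) was chosen after seeing the data; all others were planned. Of 76 calls of named genes between genotypes 12 were kept under every alternative other than the 2-fold limit, which was not applied to single genes. Of these 12, Cap1 (log2 0.85) and Arsa (0.95) in Neg and Extl3 (-0.98) in High changed by less than 2-fold. Between genotypes 0 called genes changed sign in any gate. Where counts moved by over 1.5 times, the stricter limit by its construction lowers those of the 2-fold limit; elsewhere the cause was not tested. Rises and falls in the order High, Mid and Neg were 9 and 9, 11 and 48, and 20 and 16. A model of the compared groups alone gave 1 and 2 in High, 1 and 2 in Mid and 14 and 24 in Neg. Array weights gave 48 and 48, 128 and 139, and 53 and 38. DESeq2 gave 37 and 47 in High and 42 and 137 in Mid. The 2-fold limit gave 5 and 5 in High, 6 rises in Mid and 8 falls in Neg. Without the 3 libraries there were 22 and 17 in High, and 17 of 18, 32 of 59 and 36 of 36 calls were kept in High, Mid and Neg. Among named genes and lists those that ended were Haus4 and core histone genes in High and Ctc1, Lgi4, Lpar2, Nog, Rem1, Slc41a2, Sox7, Tpbgl and Wfdc1 in Mid (adjusted p 0.0811 to 0.603). In Neg 13 genes rose with a pseudocount of 5 and 9 with edgeR, whose split there was 9 against 14. With equal totals the High split was 10 against 6. Quantile normalisation put the median log2 change of all genes between WT High and Neg at -0.0926, against 0.0176. DESeq2 gave no adjusted p for up to 1144 genes of a contrast, and these were not counted as lost.

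Gate counts moved under the 2-fold limit, to 3125, 2144 and 1875 in WT (High and Neg, Mid and Neg, High and Mid) and 2986, 2101 and 2027 in ΔHx, from 6532, 4834, 3593, 6263, 5053 and 3769. Leaving out 1 of the compared libraries gave 5557 to 6269, 3751 to 5071 and 2763 to 3388 in WT and 5303 to 5790, 3848 to 4715 and 2919 to 3412 in ΔHx. It gave 4 to 13 rises (fewest without ΔHx High replicate 1) and 3 to 12 falls (fewest without ΔHx High replicate 3) in High. It gave 3 to 15 rises (without ΔHx Mid replicate 1 and WT Mid replicate 2) and 9 to 117 falls (without ΔHx Mid replicate 2 and WT Mid replicate 2) in Mid. In Neg there were 8 to 30 rises (without ΔHx Neg replicate 1 and WT Neg replicate 1) and 2 to 13 falls (fewest without WT Neg replicate 3). Genotype effects that differed between gates numbered 0 to 2 for High against Neg, and 0 to 24 for High against Mid and for Mid against Neg (24 without WT Mid replicate 2). DESeq2 gave 6, 28 and 19 for the 3. For High against Mid, main count 2, there was 0 with a pseudocount of 0.5, with a filter at 50 and with the compared groups alone, 1 with no filter, with robust variances and with edgeR, 4 with array weights and 9 without the 3 libraries. For Mid against Neg, main count 1, there was 0 with a pseudocount of 0.5, a filter at 50 and edgeR, 2 with a pseudocount of 5, 6 with array weights and 14 without the 3 libraries.

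Same-numbered samples correlated at -0.171 to 0.291 over all contrasts and did not all pass 0.1, so the replicate block was kept as an alternative. All negative values came from genotype contrasts. In gate contrasts they ran from 0.0156 (ΔHx High and Neg) to 0.291 (WT High and Mid), and 6 of 6 samples in each correlated best with their own number. This hints that equal numbers within a genotype shared a pool, which the main tests ignored. The cholesterol calls in Mid and Neg, which both ended without replicate 3 of WT, may thus rest on the same pool. In genotype comparisons within a gate the block joined WT and ΔHx libraries of equal number, which correlated at only -0.171 to 0.0820. There it therefore does not test pools shared within a genotype. The block gave 12 and 13, 12 and 52, and 22 and 14 rises and falls in High, Mid and Neg. It gave 0, 5 and 7 genes whose genotype effect differed between gates. Among calls of named genes and lists between genotypes it ended those of Lpar2 and Haus4 in High, Ctc1, Lgi4 and Sox7 in Mid, and Hmgn2, Spag6l and the hypoxia and glycolysis list in Neg (adjusted p 0.0525 to 0.0657).

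Lists called between genotypes numbered 20, 0 with an estimated correlation, 2 with fry, which tests only whether a list moves, and 16 to 25 with 1 library left out. Gate gene sets numbered 2, 0 with an estimated correlation and 0 with fry, and 1 to 2 with 1 library left out. The Foxa2 change in High was 0.01 to 0.35 with 1 library left out. Directions of single genes, or of the tests of lists and sets, turned for the values that follow. The Foxa2 change in Mid became 0.0508 in edgeR, 0.0512 in DESeq2, 0.19 without ΔHx Mid replicate 1, 0.11 without ΔHx Mid replicate 2, 0.0670 without WT Mid replicate 1 and 0.0161 without WT Mid replicate 2 (lowest -0.39 without ΔHx Mid replicate 3), and its difference between High and Mid became -0.0417 without ΔHx Mid replicate 1 (highest 0.54 without ΔHx Mid replicate 3). The test of ribosomal genes in Mid turned downward without ΔHx Mid replicate 3 (median 0.00654) and WT Mid replicate 3 (0.00513; highest 0.128 without WT Mid replicate 1). That of genes lower in WT High than Neg turned in Mid without ΔHx Mid replicate 1 (-0.0126) and WT Mid replicate 1 (-0.0278; highest 0.0802 without ΔHx Mid replicate 3). That of genes lower in WT High than Mid turned in Neg without the 3 libraries (-0.00117), ΔHx Neg replicate 2 (-0.0121), ΔHx Neg replicate 3 (0.0149) and WT Neg replicate 1 (-0.00226). Depth limits genes with few reads, where 1 to 3 reads decide a ratio.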

Other observations

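The tests below of FoxA2 activity, linked variants, strain variants and a share of High gate cells were chosen after results they measure had been seen in part. In WT embryos Dnmt3b, a DNA methyltransferase of the epiblast, was 4270 ± 628 in High, 7763 ± 768 in Mid and 15021 ± 1116 in Neg (n = 3), and the dioxygenase Tet3 was 1490 ± 155, 606 ± 69.3 and 411 ± 71.2. Between High and Neg 6 of 28 chromatin genes rose and 12 fell, and the list was not called (adjusted p = 0.318). Over the same step 18 of 20 S phase genes fell (median -0.75, adjusted p = 1.81e-09; adjusted p = 0.104 with an estimated correlation), with Rrm2 at 3383 ± 497 against 8511 ± 111. Of 23 epithelial junction genes 21 rose (median 1.67, adjusted p = 2.11e-14; adjusted p = 0.0531 with an estimated correlation), with Krt8 at 25455 ± 3471 against 2525 ± 245. Mesenchymal genes went the other way, 14 of 17 falling (adjusted p = 0.0152 with an estimated correlation), among them Pdgfra (98.9 ± 44.2 against 2301 ± 202).

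Some genotype differences recurred across gates. If they needed FoxA2 in the sorted cells, the Neg effect would be small beside the High effect, but over the 18 genes called in High the median ratio of Neg to High log2 change was 0.626 (quartiles 0.0732 to 0.923), with Cap1, Nr1h5 and Lpar2 near 1, Alox15 at 1.36 and Dll1, Gprc5a and Tyro3 near 0, so this genotype effect stays open for part of the genes. These genes were picked by their High change, which can raise that change and lower the ratio. The direct limma test of High against Neg called 0 genes, so ratios near 0 do not show an effect limited to High. A linked variant that acts only on genes near the targeted locus cannot account for most of the recurrent genes. Of the 13 with a position 2 lay on the chromosome of Foxa2 and 0 lay within 20 Mb of it (one-sided Fisher exact p = 1). These 2 were Tmem87a (start 120355312) and Gm14403 (start 177498215), with Foxa2 at 148042877. Positions cannot decide on a linked variant that changes genes elsewhere through a regulator. Strain variants elsewhere that differ between the lines may be the cause of genes such as Nr1h5. Within 5 Mb lay 1 pair of recurrent genes, against a 95th percentile of 2 in 10000 random sets. Unlinked variants would leave no cluster, so this cannot be told apart from the deletion here. Pairs with genes called in 1 gate did not enter that count, such as Hyou1 (end 44392369) and Slc37a4 (start 44396852) on chromosome 9. Another was Gprc5a (end 135084709) and Hebp1 (start 135137522) on chromosome 6. These pairs were picked from the positions and were not tested.

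The node and ciliary lists were called higher in ΔHx Neg, with 2 of 16 and 1 of 25 members rising (adjusted p = 0.184 and 0.457 with an estimated correlation). A small share of High gate cells in those libraries may be the source. High-specific genes were taken as those with a mean of at least 200 in High, at least 4 times Mid, and Neg at most 0.05 of High; of these 103 genes 87.4% held a larger share of their High value in ΔHx Neg than in WT Neg, by a median of 0.833% of the High value (quartiles 0.383 to 1.404). Node and ciliary genes such as Shh and Foxj1 meet these limits and were not left out, so this share partly restates the rise that it was to explain. The libraries overlapped, with median shares of 3.04%, 2.99% and 1.33% in ΔHx Neg and 1.92%, 0.956% and 1.25% in WT Neg, which keeps the question open. Foxa2 itself was not among the 103 genes. In Neg it was 53.6 ± 9.65 in ΔHx and 28.2 ± 10.9 in WT, a rise in the same direction that was not called. An effect of the deletion on cells without FoxA2 signal was not tested.

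Other splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.05. The real split, 1 of 10 in each case, called 18 genes in High (highest other split 1), 59 in Mid (2) and 36 in Neg (15) between genotypes. It called 6532 (0), 4834 (1) and 3593 (1) between WT High and Neg, Mid and Neg, and High and Mid, and 6263 (2), 5053 (0) and 3769 (1) in ΔHx. For genotype effects that differ between High and Neg the real count was 0, so that all 100 of 100 drawn splits called as many by construction (highest other 60), which decides nothing. For the other pairs of gates chance was not excluded: 8 of 100 called as many as the 2 for High against Mid and 19 as many as the 1 for Mid against Neg (highest other 61). The draw allowed the genotype labels to be exchanged in 1 gate only. A genotype difference shared by both gates then counts as a difference between gates, so these shares do not measure chance alone. For High against Mid the highest other split called 1142, far above the real count of 2, and the source of this was not traced.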
